A study of Mus musculus with 11 samples.

How the data were processed

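The 11 arrays were Affymetrix 3' expression arrays of mouse beta cell RNA. Per the labels' protocols, total RNA was isolated with PicoPure and labelled as biotinylated aRNA. Per the submitters' processing notes, probe set values were made with RMA in Affymetrix Expression Console, version not given. The deposited values are log2 intensities and were used as deposited. Whether all arrays went through RMA in the same run is not stated. Raw image files were not used here.

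The array carried 45101 probe sets, of which 34958 named 1 gene, 932 named several and 9211 named none, and 64 were controls. Each of 18194 genes was represented by the probe set with the highest mean over the 11 arrays, and 9012 genes had more than 1. A gene was kept when its value was above the median of all values (3.863) on at least 3 of the 11 arrays, which left 13366. Genes without a probe set naming them alone were not analysed here. A reference genome was not used here.

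Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 term per age and no further factor. P-values were adjusted by the Benjamini-Hochberg method over the genes kept, at a threshold of 0.05. An F test covered the 3 ages together. Gene lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, and were adjusted over 23 lists. Where a count is given as adjusted over the list alone, the p-values of its members were adjusted among themselves. Groups were said not to overlap when every value of the first lay beyond every value of the second.

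The 24 lists were beta cell identity and maturity, disallowed or immature beta cell, secretory granule and exocytosis, proliferation, cell cycle inhibition and DNA damage, senescence-associated secretory, markers the study followed, insulin and IGF signalling, imprinted growth network, unfolded protein response, oxidative phosphorylation, antioxidant, interferon response and class I MHC, dissociation and immediate early stress, alpha, delta and PP, acinar, duct, endothelial, myeloid, lymphoid, stellate and fibroblast, Schwann and red blood cell. They were written from general knowledge of these genes, except that the markers the study followed were recalled from the study. How the study chose them is not stated in the labels. Lists with fewer than 3 genes kept were not tested.

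Genes were named by rule: the 6 largest rises and the 6 largest falls among genes that passed with groups that did not overlap, or the 3 with the smallest p-value in a direction where fewer than 3 passed; up to 4 members of each list in order of p-value; the hormone genes; and the markers the study followed. Genes outside this rule are said to have been chosen after their values were seen.

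The groups, the model, the filter, the lists and a first set of other settings were fixed before the data were examined. That set held no filter and a stricter filter (the 60th percentile), median centring, quantile normalization again, cyclic loess, the mean of a gene's probe sets, probe sets without marks of cross-hybridisation, probe sets one by one, an intensity trend with robust variance, array weights, a threshold of 1.5-fold, a replicate block, leaving out each array, fitting only the groups compared, an estimated correlation and fry. The settings that use the hybridisation controls or leave out arrays by their quality were chosen after seeing the data. They were the control class as a block, the control mean as a covariate, the block without young replicate 3, the fit without young replicate 3 and 2yo replicate 4, only the 4 arrays with high controls and only the 7 with low controls. In the blocked fit 1yo is compared with young through the 2yo group, the only age with arrays of both classes, so that contrast rests on 2yo replicate 4.

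The fit was tested on simulated data with known changes in some genes. With the spread of the real arrays, limma found 5.97% of log2 changes of 1, 73.1% of changes of 2 and 93.9% of changes of 3 between 1yo and young. Between 2yo and young it found 19.4%, 71.6% and 87.9%, and between 2yo and 1yo 22.4%, 74.6% and 93.9%. False calls among 13166 unchanged genes were 12, 32 and 0. A shift of 1 put on the oxidative phosphorylation list led to 1 of 23 lists being called. The simulated noise was independent between genes, so false calls among genes or lists that move together were not measured.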

Results

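RNA was profiled from pancreatic beta cells of C57Bl/6 mice at 3 ages. The cells carried MIP:GFP, a transgene in which the mouse insulin promoter drives green fluorescent protein, and were purified by fluorescence-activated cell sorting (FACS). The young group held 3 arrays, from mice aged 3.5 to 9 weeks. The 1yo and 2yo groups, aged 1 and 2 years, held 4 arrays each. Each sample was read on 1 Affymetrix 3' expression array, and the deposited values are log2 probe set intensities. The number of arrays limits the precision of every estimate, and the p-values measure spread between samples, because the labels do not say whether the samples came from separate animals.

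The arrays differed in more than age. The hybridisation controls, bacterial and phage transcripts added to each labelled sample at a fixed amount, averaged 13.05 to 14.26 on 4 arrays (the 3 young arrays and 2yo replicate 4) and 10.36 to 11.38 on the other 7. The first principal component held 78.8% of the variation and parted the same 4 arrays from the 7. The median of all probe set values averaged 4.065 in young, 3.7 at 1yo and 3.774 at 2yo. Their upper quartile averaged 5.089, 5.699 and 5.591. The young arrays thus read higher in the middle of the range and lower towards its top, and the list tests did not match genes on level. Acinar enzyme transcripts, from the digestive cells that surround the islets, had a list mean of 12.77 and 12.75 in young replicates 1 and 2 and 13.21 in 2yo replicate 4. Their means in the 4 1yo arrays were 5.21 to 10.35, in young replicate 3 it was 5.15, and in 2yo replicates 1, 2 and 3 they were 3.64 to 4.43. Young replicate 3 correlated with the other arrays at r of 0.47 to 0.67 across genes, which are not independent replicates, and its Actb probe sets differed by 1.437 between the 3' and 5' ends, against 4.323 to 4.735 on the other 10 arrays. Because age and control level go together on 10 of the 11 arrays, each comparison with young is given with and without the control class as a block. That block rests on 2yo replicate 4, the only array of an older group with high controls.

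For some named genes every array of a group lay at or below the highest Bacillus control probe set, taken as a background level (array medians of these probe sets 2.39 to 3.21), so the changes against that group are lower limits in size. These were Hspa1a, Ifit1 and Lcn2 in young, Lcn2, Cenpe, Col1a1, Dcn, Kcnq5, Pdgfra, Ptf1a and 2810408B13Rik at 1yo, and Pdgfra and Slc4a1 at 2yo.

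The 1yo and young arrays were compared to ask how beta cell transcripts differ between young and middle-aged mice. Tph1, the enzyme that starts serotonin synthesis, rose from 3.94 ± 0.45 (SD, n = 3) to 10.17 ± 0.26 (SD, n = 4), the largest rise (log2 change 6.24, SE 0.955), although in young it was above the highest Bacillus control probe set on only 1 of 3 arrays, so that its size is uncertain. The heat shock chaperones Hspa1a and Hspa1b rose by 4.47 (SE 0.38) and 4.36 (SE 0.36). Gbp2, an interferon-induced GTPase, fell by 2.56 (SE 0.42) on a probe set marked for cross-hybridisation, while its other probe set did not pass (log2 change -0.78, adjusted p = 0.232). Tspan8, a tetraspanin found in duct cells, rose by 3.12 (SE 0.28). For Hspa1a, Hspa1b, Gbp2 and Tspan8 the change kept its direction and its call with the control class as a block. The blocked log2 changes were 3.87, 4.23, -4.08 and 2.77, with adjusted p from 0.016 to 0.0386. For Tph1 the blocked change was 1.60 with an adjusted p of 0.125. That contrast adds 1yo minus 2yo replicates 1, 2 and 3 to 2yo replicate 4 minus young. Hspa1a, Hspa1b and Gbp2 also passed between 2yo and 1yo, so their kept calls partly restate that comparison. The Gbp2 mean was 3.845 at 1yo and 7.335 in 2yo replicates 1, 2 and 3.

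Of 13366 genes tested with limma, 8820 passed an adjusted p of 0.05, 6768 up and 2052 down. After cyclic loess the balance turned, with 2577 up and 2813 down, and after quantile normalization it was 3424 up and 2261 down. Cyclic loess removes offsets between arrays along intensity, so an even balance and a median near no change follow from the method. It cannot tell a change of most genes with age from a technical offset. The median log2 change over the genes tested was itself 0.95, so a gene at that value stands in the middle of their distribution. Without the filter on dim genes it was 0.13 over 18194 genes. Below, "all genes" stands for the genes tested. This median was 1.34 after centring each array on its median, 0.33 after quantile normalization and -0.01 after cyclic loess. The 1yo and young values did not overlap for 70.8% of genes, where chance gives 5.71%. With the control class as a block 92 genes passed, 73 up and 19 down, and 68 of them had passed in the same direction without it.

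The other large rises were in Clns1a, which takes part in assembly of the splicing machinery (5.39), the kinetochore gene Zwint (5.34), the cytoskeletal linker Dst (5.32), the growth arrest gene Gadd45g (5.20) and the Wnt signalling gene Dvl1 (5.13). The largest falls were in Ppox, an enzyme of heme synthesis (-5.18), the pancreatic lectin Reg3b (-5.16), the spindle assembly factor Tpx2 (-4.90), Aif1l (-4.80), Nrsn2 (-4.66) and Cryl1 (-4.53). None of these 11 passed with the control class as a block, and Reg3b, which also missed the threshold after median centring (adjusted p = 0.0558), then turned to 4.07. For Cryl1 the 3 other probe sets gave 1.81, 1.65 and 2.68, and the mean of its probe sets changed by 0.40. Ppox had another probe set at 2.00 and Dst a dimmer one at -0.585.

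Most beta cell transcripts read higher at 1yo in the deposited values. These are bright genes, and the upper quartile of all values was also lower in young (5.089 against 5.699 at 1yo), which the list tests do not separate. Of 20 measured genes of beta cell identity and maturity 19 rose, 0 fell and 1 did not pass (19 and 0 adjusted over the list alone), among them the transcription factors Nkx6-1 (2.90, adjusted p = 0.000415) and Neurod1 (2.91, adjusted p = 0.00135). Their median was 1.86 above that of all genes (adjusted p = 0.00561, and adjusted p = 0.617 with an estimated correlation). Of 20 secretory granule and exocytosis genes 18 rose, 0 fell and 2 did not pass (18 and 0 adjusted over the list alone), including the exocytosis protein Snap25 (3.52). That list stood 1.28 above all genes (adjusted p = 0.00501, and adjusted p = 0.617 with an estimated correlation). With the control class as a block the medians of both lists were 1.30 and 1.37, with adjusted p of 0.0488 and 0.0154 (both 0.909 with an estimated correlation) and 0 members passing singly, and after cyclic loess they were 0.29 and 0.15 (adjusted p of 0.247 and 0.584).

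Of the 27 unfolded protein response genes 25 rose, 0 fell and 2 did not pass (25 and 0 adjusted over the list alone). They included Eif2ak3, the stress kinase PERK (4.02), and the chaperone Hsp90b1 (4.33), and the list median was 1.97 above that of all genes (adjusted p = 0.00501, and 1.35 with adjusted p = 0.374 in the blocked fit). Of 36 oxidative phosphorylation genes 29 rose, 0 fell and 7 did not pass (31 and 0 adjusted over the list alone), with Sdhc of complex II at 4.34 and Ndufs1 of complex I at 3.29. Their median of 2.44 turned to -0.20 after cyclic loess, was 1.49 above all genes (adjusted p = 0.00561) and was 1.69 in the blocked fit (adjusted p = 0.0154). Of 18 insulin and IGF signalling genes 14 rose, 0 fell and 4 did not pass (14 and 0 adjusted over the list alone), led by the receptor Igf2r (3.77), with an adjusted p of 0.039 for the list and 0.632 in the blocked fit. Of 16 dissociation and immediate early stress genes 11 rose, 0 fell and 5 did not pass (11 and 0 adjusted over the list alone). Egr1, an immediate early transcription factor, rose by 4.66, and the list had an adjusted p of 0.0363, a call that was lost in the blocked fit, where the test pointed down. All 4 lists had an adjusted p of 0.617 with an estimated correlation. After quantile normalization the insulin and IGF signalling list (adjusted p = 0.396) and the dissociation list (0.064) no longer passed. After cyclic loess 0 lists rose and 4 fell, so none of the 6 rising lists kept its call, and Nkx6-1, Neurod1 and Ndufs1 lost theirs (adjusted p of 0.252, 0.28 and 0.0877).

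Proliferation genes moved both ways, 6 up and 9 down with 10 not passing out of 25 (6 and 9 adjusted over the list alone). The motor protein Cenpe fell by 1.54 and the spindle gene Hmmr by 3.97, while the nucleotide reductase subunit Rrm2 rose by 1.82. The list stood 1.44 below all genes (median minus that of all genes -1.44, adjusted p = 0.00338, adjusted p = 0.535 with an estimated correlation), and its median was -0.52 in the blocked fit (adjusted p = 0.0154). Of 15 genes disallowed in mature beta cells or marking immature ones, 1 rose, 5 fell and 9 did not pass (1 and 3 adjusted over the list alone). The growth factor receptor Pdgfra fell by 1.59 and the neuropeptide Npy rose by 1.33. The Npy call was lost after quantile normalization (adjusted p = 0.071) and cyclic loess (log2 change 0.0872, adjusted p = 0.802). The list's adjusted p was 0.00473, which became 0.374 in the blocked fit. Of 15 senescence-associated secretory genes 1 rose, 3 fell and 11 did not pass (1 and 1 adjusted over the list alone), and the list median of -0.30 (adjusted p = 0.00561) stood at 0.06 after median centring, where the test against other genes still passed downward (adjusted p = 0.00644), and at 0.16 in the blocked fit (adjusted p = 0.372). The last 2 lists had an adjusted p of 0.617 with an estimated correlation. Neither passed after cyclic loess (adjusted p of 0.226 and 0.227), nor did the senescence list after quantile normalization (0.064).

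Of the lists for other cells 4 passed downward at 1yo, on arrays that also differed in acinar content. Of 11 stellate cell and fibroblast genes 0 rose, 9 fell and 2 did not pass (0 and 9 adjusted over the list alone), with the collagen gene Col1a1 down by -2.02 and the proteoglycan gene Dcn by -2.80 (list adjusted p = 2.17e-05, and -0.94 with adjusted p = 0.0488 in the blocked fit). Of 17 acinar genes 1 fell, the transcription factor Ptf1a (-2.25, against 0.59 in the blocked fit), and 16 did not pass (0 and 0 adjusted over the list alone). The acinar median of -2.25 (adjusted p = 0.00473) turned to 7.28 in the blocked fit (adjusted p = 0.000906, and adjusted p = 0.909 with an estimated correlation). Of 17 myeloid genes 1 rose, 1 fell (Laptm5, -3.09) and 15 did not pass (0 and 1 adjusted over the list alone), and the list median of -0.26 (adjusted p = 0.0143) stood at 0.105 after median centring, where the test still passed downward (adjusted p = 0.00766), and turned to 1.30 in the blocked fit. Of 7 lymphoid genes 0 rose, 4 fell and 3 did not pass (0 and 3 adjusted over the list alone; adjusted p = 0.0072, and 0.82 in the blocked fit). With an estimated correlation each of these 4 lists had an adjusted p of 0.617, and 0 of the 23 lists passed by camera in that form (1 at an unadjusted p under 0.05). In the blocked fit no list passed with an estimated correlation either (adjusted p of 0.0526 or more).

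The remaining lists did not pass by camera at 1yo. Of 20 genes of cell cycle inhibition and DNA damage 11 rose, 1 fell and 8 did not pass (11 and 1 adjusted over the list alone; list adjusted p = 0.162), with Trp53inp1, a target of p53, at 4.06 and Gadd45b at 4.81. Of 21 antioxidant genes 14 rose, 1 fell and 6 did not pass (14 and 1 adjusted over the list alone; list adjusted p = 0.101), with the metallothionein Mt1 at 4.18. Of 23 interferon response and class I MHC genes 11 rose, 1 fell and 11 did not pass (10 and 1 adjusted over the list alone), and their median of 1.23 (list adjusted p = 0.746) turned to -0.33 after cyclic loess and to -0.95 in the blocked fit (adjusted p = 2.67e-10, and adjusted p = 0.0526 with an estimated correlation). The adjusted p was 0.544 for 10 imprinted growth genes (5 rose, 2 fell), 0.598 for 5 alpha cell genes (1 rose, 1 fell), 0.209 for 5 delta and PP cell genes (0 and 0, with a fall that passed after quantile normalization, adjusted p = 0.0344), 0.687 for 5 duct genes (2 rose, 0 fell), 0.113 for 7 endothelial genes (1 rose, 2 fell) and 0.148 for 3 Schwann cell genes (0 rose, 1 fell). These counts were the same when adjusted over each list alone. For the imprinted, interferon and alpha lists the test, which is relative to other genes, pointed down while the median and mean were above 0. For the delta and PP list the median was 0.09 and the mean -0.145, and for the duct list -0.33 and 0.72, with both tests pointing down. Of the red blood cell list only Slc4a1 was measured above the filter, too few for a test, and it fell by 1.23.

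Samples of 2yo and young mice were compared to ask the same question of old age. Zwint rose by 5.18 (SE 0.84) from 4.55 ± 0.52 (SD, n = 3) to 9.73 ± 1.99 (SD, n = 4). The p53 target Trp53inp1 rose by 4.01 (SE 0.40), from 3.93 to 7.94, while its other, dimmer probe set changed by -0.85 (adjusted p = 0.0513) and by -1.08 at 1yo (adjusted p = 0.0159). Chac1, a glutathione-degrading enzyme induced by endoplasmic reticulum stress, rose by 4.02 (SE 0.71). Tspan8 rose by 2.40 (SE 0.28). These 4 kept their direction and call in the fit with the control class as a block (2.19, 3.30, 1.43 and 2.14, adjusted p from 0.0321 to 0.0444). That fit here sets 1 array, 2yo replicate 4, against the 3 young arrays and takes its spread from the other groups as well. The kept calls therefore rest on that array and on the spread of the others.

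In all 7225 genes passed, 5825 up and 1400 down, around a median change of 0.77 over the genes tested, which was 1.08, 0.27 and -0.01 under median centring, quantile normalization and cyclic loess. Without the filter on dim genes the median was 0.10, and after cyclic loess 1866 genes passed up and 2071 down. The groups did not overlap for 37.0% of genes, where chance gives 5.71%. In the blocked fit, which rests on the 4 arrays with high controls for this comparison, 191 passed (171 up, 20 down), 173 of them shared with the unblocked fit in the same direction. With the control mean as a covariate 3 genes passed. The count was 3890 when only the 2 groups were fitted, 4337 after quantile normalization and 9420 without 2yo replicate 4.

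The other largest rises were in Erdr1 (5.07), the interferon-induced gene Ifi27 (5.06), Mt1 (4.81), the mitochondrial ubiquitin ligase gene Marchf5 (4.73) and Clns1a (4.67). For Erdr1 the probe set without a mark of cross-hybridisation gave -2.05. The largest falls were in Aif1l (-3.93), Tpx2 (-3.87), Nrsn2 (-3.75), the urinary protein gene Mup10 (-3.72), 2810408B13Rik (-3.63) and Cryl1 (-3.56, against 0.28 for the mean of its probe sets). None of these 11 passed in the blocked fit (adjusted p from 0.0988 to 0.504).

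Of the 20 beta cell identity genes 12 rose, 0 fell and 8 did not pass (12 and 0 adjusted over the list alone), with the transcription factor Isl1 at 3.21 and Nkx6-1 at 1.93, which turned to -0.11 after cyclic loess. The list median of 1.90 (1.13 above all genes, adjusted p = 0.0258) turned to -0.17 after cyclic loess and was 0.80 in the blocked fit (adjusted p = 0.345). Of the 20 secretory genes 17 rose, 0 fell and 3 did not pass (17 and 0 adjusted over the list alone), including the calcium channel gene Cacna1d (2.41). Their median of 1.86 (adjusted p = 0.00466) turned to -0.13 after cyclic loess and was 1.19 in the blocked fit (adjusted p = 0.0223). Of the 27 unfolded protein response genes 21 rose, 0 fell and 6 did not pass (23 and 0 adjusted over the list alone). Edem1, which helps to degrade misfolded proteins, rose by 2.48 and the stress transcription factor Ddit3 by 3.81. That list was 1.86 above all genes (adjusted p = 0.00212, and 0.029 in the blocked fit, where Edem1 at 1.35 and Chac1 passed singly). Of the 36 oxidative phosphorylation genes 26 rose, 0 fell and 10 did not pass (31 and 0 adjusted over the list alone), with Ndufs1 at 2.90. The median was 2.33 (adjusted p = 0.00212, and 0.00405 in the blocked fit), and it turned to -0.19 after cyclic loess (adjusted p = 0.608). Each of these lists had an adjusted p of 0.631 with an estimated correlation.

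Of 21 antioxidant genes 14 rose, 1 fell and 6 did not pass (15 and 1 adjusted over the list alone; list adjusted p = 0.0298, and 0.029 in the blocked fit), with the metallothionein Mt2 at 4.30. Of 23 interferon and class I MHC genes 17 rose, 0 fell and 6 did not pass (18 and 0 adjusted over the list alone). The peptide transporter Tap1 rose by 2.23 and the class I gene H2-K1 by 4.37. The interferon list was 1.33 above all genes (adjusted p = 0.0289, and 0.0514 after median centring), with a median of 0.13 in the blocked fit (adjusted p = 0.744). Of 25 proliferation genes 3 rose, 8 fell and 14 did not pass (3 and 8 adjusted over the list alone), with Cenpe down by -1.20 and the cytokinesis gene Prc1 by -1.22 (list adjusted p = 0.000399, and 0.00371 in the blocked fit). Of 20 genes of cell cycle inhibition and DNA damage 11 rose, 0 fell and 9 did not pass (11 and 0 adjusted over the list alone; list adjusted p = 0.207). The cell cycle inhibitor Cdkn1a rose by 1.71, which turned to -0.23 after cyclic loess, and the p53 regulator Mdm2 and the cyclin gene Ccng1 rose by 1.90 and 2.54. Dimmer probe sets of Mdm2 and Tap1 passed the other way (-0.909 and -0.95). With an estimated correlation the adjusted p was 0.324 for proliferation and 0.631 for the antioxidant and interferon lists. After cyclic loess the interferon list was the only one of the 23 to rise, and 4 fell. Cacna1d, Edem1, Ndufs1 and Cdkn1a then lost their calls (adjusted p of 0.183, 0.509, 0.144 and 0.612), and after quantile normalization the beta cell identity, secretory and antioxidant lists did (each with an adjusted p of 0.0548).

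The acinar list had the lowest median, -3.99, with 0 of 17 members passing either way (0 and 0 adjusted over the list alone; list adjusted p = 9.37e-05), and this median turned to 3.25 in the blocked fit. Without 2yo replicate 4, which carried the highest acinar values, 16 of 17 fell. Of 11 stellate and fibroblast genes 0 rose, 8 fell and 3 did not pass (0 and 9 adjusted over the list alone; list adjusted p = 1.82e-05, and 0.0192 in the blocked fit), with Col1a1 down by -1.66. Of 17 myeloid genes 1 rose and 1 fell with 15 not passing (1 and 1 adjusted over the list alone; list adjusted p = 0.00212), and the median of -0.65 turned to 0.80 in the blocked fit. Of 7 lymphoid genes 0 rose, 3 fell and 4 did not pass (0 and 3 adjusted over the list alone; list adjusted p = 0.0124, and 0.995 in the blocked fit). Of 15 disallowed or immature genes 1 rose, 3 fell, among them Pdgfra (-1.58), and 11 did not pass (1 and 3 adjusted over the list alone). The median of that list, -0.26, stood at 0.07 after median centring, where the test still passed downward (adjusted p = 0.0145; list adjusted p = 0.00685, and 0.345 in the blocked fit). These 5 lists had an adjusted p of 0.631 with an estimated correlation, and 0 of the 23 lists passed by camera in that form (1 at an unadjusted p under 0.05). In the blocked fit no list passed with an estimated correlation either (adjusted p of 0.532 or more).

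Of the lists that did not pass by camera, 18 insulin and IGF signalling genes had 13 rising and 0 falling (14 and 0 adjusted over the list alone; list adjusted p = 0.0639), with Igf2r at 3.04. The 16 dissociation genes had 9 rising and 0 falling (9 and 0 adjusted over the list alone; list adjusted p = 0.207), with Egr1 at 3.97. Of 15 senescence-associated secretory genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; list adjusted p = 0.203). The list adjusted p was 0.576 for imprinted growth genes (5 rose, 2 fell, with Dlk1 at -1.05), 0.498 for alpha (1 rose, 1 fell), delta and PP (0 and 0) and duct genes, 0.0724 for endothelial genes (0 rose, 2 fell, 0 and 0 adjusted over the list alone) and 0.0639 for Schwann cell genes (0 and 0). Of 5 duct genes 3 rose and 0 fell (3 and 1 adjusted over the list alone), among them Tspan8 and Lcn2, which encodes an iron-binding protein of innate defence (4.08). For the imprinted, alpha, delta and PP, and senescence lists the test pointed down while the median and mean were above 0. After median centring the tests of the endothelial list (median 0.0551, adjusted p = 0.0468) and the Schwann cell list (-0.416, 0.0471) passed downward. Slc4a1 fell by 1.32.

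The 2yo and 1yo arrays were compared to ask what differs between middle and old age. The heat shock chaperones Hspa1b and Hspa1a fell from 7.86 ± 0.62 and 7.91 ± 0.67 at 1yo (SD, n = 4) to 3.68 ± 0.28 and 3.87 ± 0.41 at 2yo (SD, n = 4). These were log2 changes of -4.18 (SE 0.34, adjusted p = 0.000878) and -4.04 (SE 0.35, adjusted p = 0.0011). The noncoding transcript Mir670hg fell by 1.94 (SE 0.21, adjusted p = 0.00824). Gbp2 rose by 3.11 (SE 0.39, adjusted p = 0.0206). For each of the 4 genes the 2 groups did not overlap.

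These were the only genes that passed among 13366 with limma, 1 up and 3 down, with 602 at an unadjusted p under 0.05. With arrays weighted by their quality 2756 passed, 1245 up and 1511 down. The median change of all genes was -0.10, and groups did not overlap for 9.29% of genes, where chance gives 2.86%. The 2yo group held 1 array with high hybridisation controls, replicate 4, and 3 with low ones. Without that array, or equally with the control class as a block, 72 genes passed (56 up, 16 down), the same 4 among them. Restricted to the 7 arrays with low controls, a comparison chosen after the data had been seen, 1488 genes passed (850 up, 638 down), and the groups did not overlap for 22.3%, where chance gives 5.71%. Of the 4 genes, Gbp2, the only one called up, no longer passed after median centring (adjusted p = 0.0608), with the mean of its probe sets, with the probe set that lacks a mark of cross-hybridisation (log2 change 2.61), with the replicate number as a block, with only the 2 groups fitted, or without any 1 of 9 arrays (all but young replicate 3 and 2yo replicate 4). Mir670hg no longer passed after quantile normalization (0.818) or cyclic loess (0.109), with the replicate number as a block (0.108), or without any 1 of 6 arrays (each 1yo replicate and 2yo replicates 2 and 3). Hspa1a and Hspa1b passed in every setting tried.

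**Figure D1:**
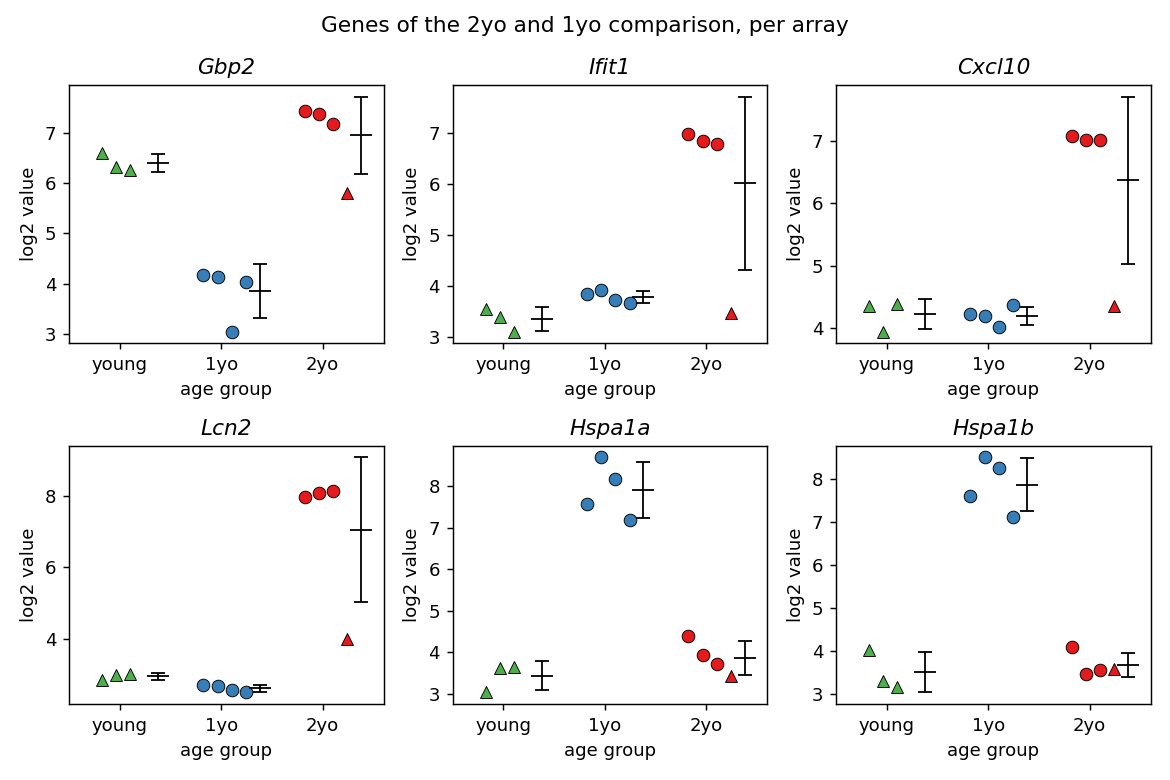
Log2 value on each array of 6 genes of the 2yo and 1yo comparison, by age group; triangles are the 4 arrays with high hybridisation controls, circles the 7 with low ones, and the dash and bar give the group mean and SD. Hspa1a and Hspa1b are high at 1yo alone, while Ifit1, Cxcl10 and Lcn2 are highest in 2yo replicates 1, 2 and 3 and lower in replicate 4.

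Interferon genes stood above the rest at 2yo. Of 23 measured members 1 rose, Gbp2, and 22 did not pass (6 and 0 adjusted over the list alone). The interferon-induced genes Ifit1, Ifit3 and Gbp3 differed by 2.23, 2.73 and 2.06 with adjusted p of 0.676, 0.424 and 0.442. In 2yo replicates 1, 2 and 3 the Ifit1 mean was 6.86, against 3.79 at 1yo and 3.48 in 2yo replicate 4. The list was 0.82 above all genes (adjusted p = 5.2e-16 by camera, adjusted p = 0.29 with an estimated correlation, and 0.405 by fry). In the blocked fit its median was 1.35 (adjusted p = 7.76e-34, and adjusted p = 0.00138 with an estimated correlation), with 7 members rising and 0 falling.

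Of 15 senescence-associated secretory genes 0 passed singly (2 and 0 adjusted over the list alone), and the list was 0.54 above all genes (adjusted p = 3.57e-07, adjusted p = 0.147 with an estimated correlation). The chemokines Cxcl10 and Cxcl1 differed by 2.18 and 1.34 (adjusted p of 0.433 and 0.424), and in the blocked fit the list median was 0.09 (adjusted p = 0.000939, and adjusted p = 0.343 with an estimated correlation) with those 2 members rising. Of 20 beta cell identity genes 0 passed (0 and 1 adjusted over the list alone), and the list lay below all genes (median minus that of all genes -0.44, adjusted p = 0.00179, adjusted p = 0.967 with an estimated correlation, and in the blocked fit 0.0445, or 0.877 with an estimated correlation). Within it the cation channel gene Trpm5 differed by -1.71 and Nkx6-1 by -0.98, with adjusted p of 0.464 and 0.903. Of 16 dissociation genes 2 fell, Hspa1a and Hspa1b, and 14 did not pass (0 and 2 adjusted over the list alone). That list had an adjusted p of 0.00179, which was 0.967 with an estimated correlation and 0.459 in the blocked fit. Of 5 duct genes 0 passed (1 and 1 adjusted over the list alone; list adjusted p = 0.0384, adjusted p = 0.29 with an estimated correlation, and in the blocked fit 0.00496, or 0.144 with an estimated correlation), with Lcn2 at 4.42 (adjusted p = 0.186). Of 5 delta and PP cell genes 0 passed (0 and 0 adjusted over the list alone; list adjusted p = 0.0384, adjusted p = 0.967 with an estimated correlation, and 0.459 in the blocked fit). With an estimated correlation 0 of 23 lists passed by camera (3 at an unadjusted p under 0.05), and 0 passed by fry (2 at an unadjusted p under 0.05).

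The other 17 lists did not pass at 2yo against 1yo. Their adjusted p was 0.0833 for disallowed or immature, 0.145 for secretory, 0.557 for proliferation, 0.503 for cell cycle inhibition, 0.999 for the markers the study followed, 0.0885 for insulin and IGF signalling, 0.828 for imprinted, 0.986 for unfolded protein response, 0.954 for oxidative phosphorylation and 0.218 for antioxidant genes. It was 0.914 for alpha, 0.375 for acinar, 0.848 for endothelial, 0.828 for myeloid, 0.178 for lymphoid, 0.0734 for stellate and 0.999 for Schwann cell genes. The stellate list passed upward after median centring (adjusted p = 0.0276) and the secretory list downward after quantile normalization (adjusted p = 0.0229). In the blocked fit the acinar list (median -4.13, adjusted p = 1.58e-10) and the myeloid list (median -0.69, adjusted p = 6.13e-06) passed downward, with adjusted p of 0.53 and 0.495 with an estimated correlation. Without the block none of the members of the 17 lists passed singly. For the proliferation, imprinted and oxidative phosphorylation lists the test pointed up while the median was below 0, and for the antioxidant, alpha, endothelial and Schwann cell lists the median was above 0 and the mean below it. Icam1, an adhesion molecule, differed by 2.50 (adjusted p = 0.083). The acinar gene Cela3b differed by -3.15 with an SE of 2.50.

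**Figure D2:**
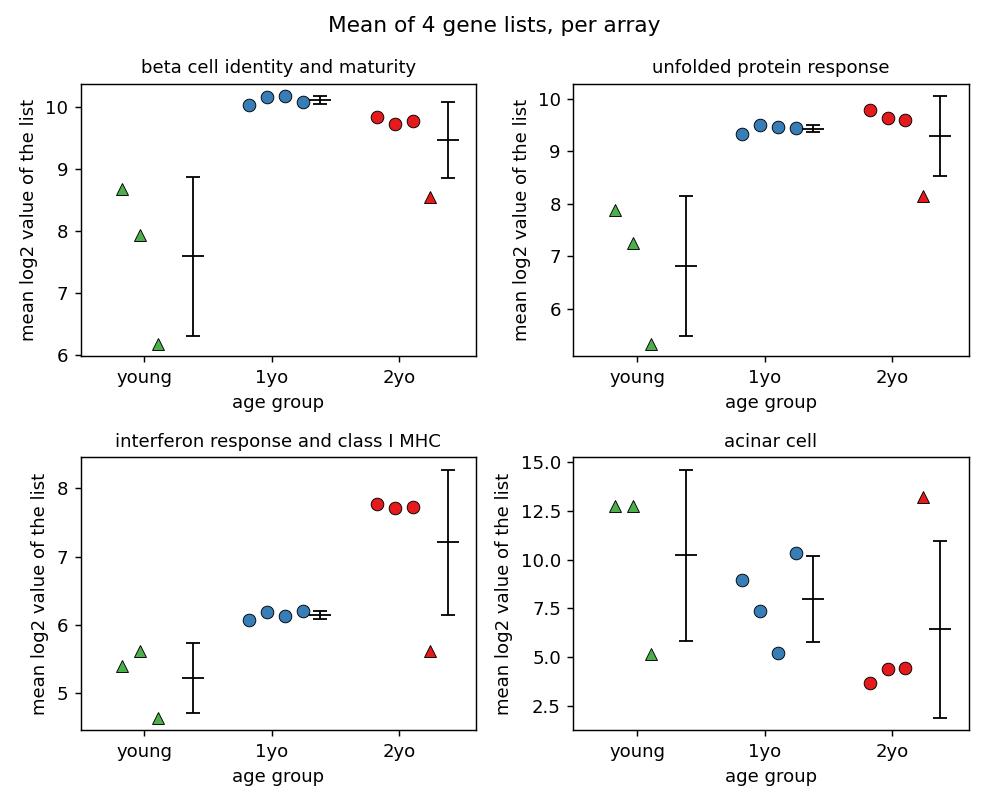
Mean log2 value on each array of 4 gene lists, by age group; triangles are the 4 arrays with high hybridisation controls, circles the 7 with low ones, and the dash and bar give the group mean and SD. The interferon mean is 7.72 to 7.78 in 2yo replicates 1, 2 and 3 and 5.62 in replicate 4, while the acinar mean is 13.21 in replicate 4 and 3.64 to 4.43 in the others.

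Among genes recalled as markers the study followed, which may have been chosen on these samples and so are not independent evidence, 4 of 6 measured rose at 1yo, 1 fell and 1 did not pass (4 and 1 adjusted over the list alone; list adjusted p = 0.514). At 2yo 4 rose, 0 fell and 2 did not pass (4 and 1 adjusted over the list alone; list adjusted p = 0.468). Bambi, a decoy receptor of TGF-beta signalling, rose by 3.63 at 1yo and 3.50 at 2yo (blocked 1.94 with adjusted p = 0.11, and 2.23 with adjusted p = 0.0372). Glb1, the lysosomal beta-galactosidase, rose by 3.34 and 2.85 (blocked 1.47 and 1.45, adjusted p of 0.491 and 0.353). Trp53bp1, a DNA damage response protein, rose by 3.48 and 2.54 (blocked 1.80 and 1.28, adjusted p of 0.566 and 0.571), and neither call held after quantile normalization (0.0623 and 0.173) or cyclic loess.

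The receptor Igf1r rose by 1.43 at both ages (adjusted p of 0.0156 and 0.0195, lost after quantile normalization at 0.135 and 0.118), which turned to -0.01 after cyclic loess at 1yo and to -0.52 and -0.03 in the blocked fit. The potassium channel gene Kcnq5 fell by 1.47 at 1yo (adjusted p = 0.00612), against 0.05 in the blocked fit, and its change at 2yo was -0.90 (adjusted p = 0.0599). The surface antigen Cd99 changed by 0.42 and 0.20 (adjusted p of 0.169 and 0.521), and at 1yo it passed after median centring (0.78, adjusted p = 0.0316) and cyclic loess (0.66, adjusted p = 0.0482). Cdkn2a, the gene of the cell cycle inhibitor p16, did not reach the filter, with 3.03 ± 0.45 in young (SD, n = 3), 3.14 ± 0.10 at 1yo (SD, n = 4) and 2.90 ± 0.19 at 2yo (SD, n = 4). Between 2yo and 1yo none of the 6 passed. The probe sets of Igf1r ranged from -0.67 to 2.59 at 1yo and those of Trp53bp1 from -0.96 to 3.48.

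**Figure D3:**
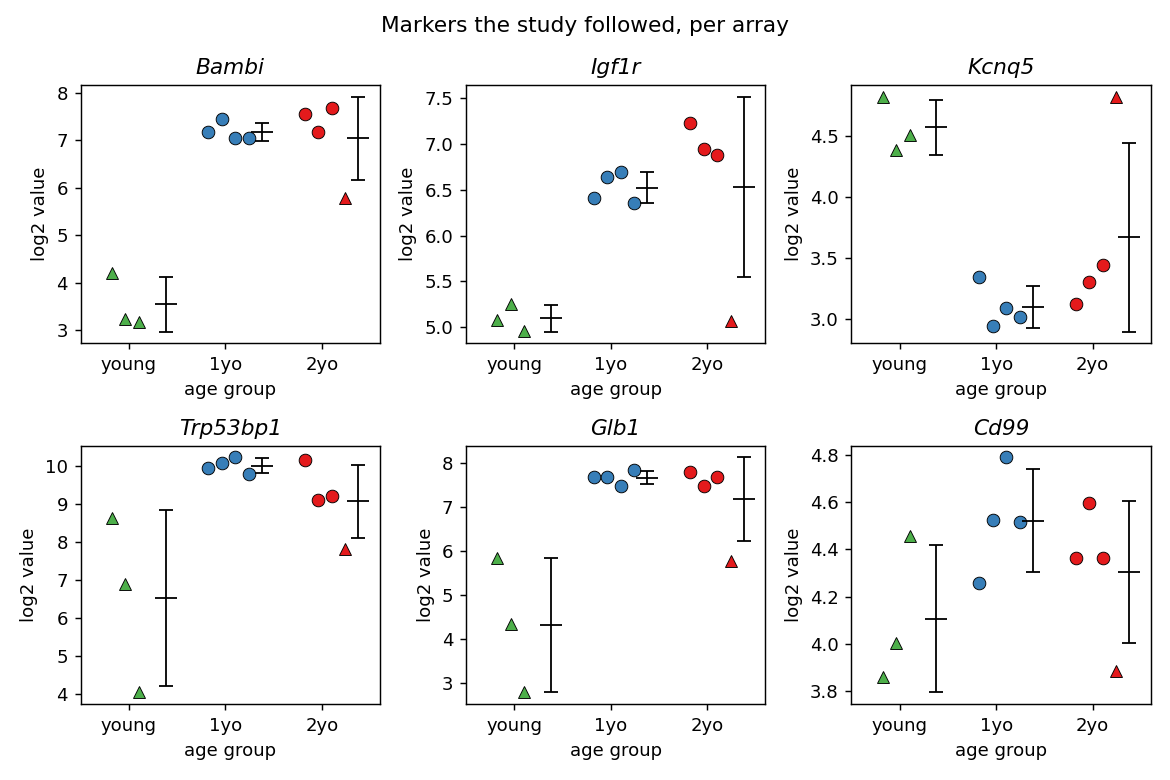
Log2 value on each array of the 6 measured markers the study followed, by age group; triangles are the 4 arrays with high hybridisation controls, circles the 7 with low ones, and the dash and bar give the group mean and SD. In Igf1r and Kcnq5 the value of 2yo replicate 4 lies beside the young arrays.

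The hormone transcripts did not pass in any comparison of the deposited values. Ins2, which encodes insulin, was at 14.66 ± 0.27 (SD, n = 3) in young and changed by 0.44 at 1yo (adjusted p = 0.106) and 0.34 at 2yo (adjusted p = 0.222). It held the highest value on each 1yo array and on 2yo replicates 1, 2 and 3, so its levels cannot be ordered, and its changes turned to -2.30 and -2.42 after cyclic loess, while after median centring the change at 1yo was 0.81 and passed (adjusted p = 0.0181). Glucagon (Gcg) changed by -0.22 at 1yo and -0.08 at 2yo against young, which turned to 0.145 and 0.216 after median centring. Somatostatin (Sst) changed by -0.93 and -0.52, which passed after quantile normalization at -2.79 and -2.22. Pancreatic polypeptide (Ppy) changed by 0.38 and 0.87, which turned to -1.45 and -0.885 after quantile normalization. After cyclic loess the falls passed for Gcg (-2.83 at 1yo and -2.43 at 2yo) and Sst (-3.44 and -2.75), and for Ppy at 1yo alone (-2.30).

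An F test over the 3 ages called 7627 genes. Of these 916 rose with each age step, 219 fell with each step, 5194 had their highest mean at 1yo and 1298 their lowest. These shapes leaned on 2yo replicate 4: without it 9336 genes were called, of which 3686 rose with each step, 1195 fell, 3355 had their highest mean at 1yo and 1100 their lowest. The 1yo and 2yo comparisons shared 5611 genes called up and 1350 called down, where independent lists would share 2950 and 214.9. Both use the same 3 young arrays, and simulated unchanged groups that share them gave a covariance of changes across genes of 0.129 and a correlation of 0.574, against 2.155 and 0.971 observed. The simulated noise was independent between genes and held no offset of whole arrays. The gap therefore cannot part a shared change with age from a shared offset of the young arrays. Such groups call almost no genes, so their overlap of 0, against 6961 observed, does not measure what the shared arrays add. With the control class as a block 158 genes passed the F test and 58 were shared.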

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

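The rule for outlying values and the splits of the arrays by age were set before the result was seen, while the comparison within the 7 arrays with low controls and the control class as a block were chosen afterwards. In groups of 4 arrays the Dixon ratio, the gap between an extreme value and its neighbour over the range, marks a value when it exceeds the 5% critical value. Of 224 groups tested 65 were marked, where chance marks about 1 in 20. In the 2yo group 60 were marked, and all 60 were 2yo replicate 4; the other 5 were in the 1yo group.

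At the level of whole arrays, 2yo replicate 4 had ratios of 0.896 for the hybridisation controls, 0.865 for the first principal component and 0.887 for the second. Its list means gave 0.911 for beta cell identity, 0.887 for disallowed or immature, 0.875 for secretory granule, 0.993 for proliferation, 0.881 for unfolded protein response, 0.866 for oxidative phosphorylation, 0.856 for antioxidant, 0.974 for interferon, 0.932 for dissociation, 0.834 for alpha, 0.918 for acinar, 0.981 for duct, 0.921 for myeloid, 0.859 for lymphoid and 0.872 for stellate genes.

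Among single genes the same array had ratios of 0.987 for Tph1, 0.955 for Clns1a, 0.95 for Zwint, 0.866 for Dst, 0.935 for Gadd45g, 0.895 for Reg3b, 0.844 for Cryl1, 0.882 for Nkx6-1, 0.914 for Cenpe, 0.896 for Hmmr, 0.882 for Gadd45b, 0.838 for Igf2r, 0.956 for Sdhc, 0.939 for Mt1, 0.849 for Gbp2, 0.909 for Egr1, 0.851 for Npy, 0.867 for Dcn, 0.883 for Ptf1a, 0.868 for Laptm5, 0.907 for Ppy, 0.837 for Igf1r, 0.842 for Glb1 and 0.834 for 2810408B13Rik. The ratios were 0.927 for Isl1, 0.838 for Cdkn1a, 0.923 for Edem1, 0.956 for Chac1, 0.927 for Ddit3, 0.932 for Mt2, 0.933 for Tap1, 0.856 for H2-K1, 0.96 for Lcn2, 0.895 for Icam1, 0.942 for Ifit1, 0.974 for Cxcl10, 0.894 for Gadd45a, 0.934 for Trib3, 0.847 for Atf3, 0.97 for Txnip, 0.868 for H2-Aa and 0.887 for Trpm5.

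In the 1yo group the ratios were 0.874 for Nkx6-1 (replicate 4), 0.846 for Trp53inp1 (replicate 1), 0.865 for Gbp2 (replicate 3), 0.906 for 2810408B13Rik (replicate 1, on values within the range of the Bacillus control probe sets) and 0.92 for Ccng1 (replicate 2). No array was removed from the fits given first.

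The groups were also set against every other way of splitting the same arrays. For 1yo against young the real split called 8820 genes and the highest of the other 34 called 0, so 1 of 35 splits reached it. That real split is also the split by hybridisation control class, so its count cannot part age from class. For 2yo against young 2 of 35 splits reached the real count of 7225. The other, with 9060 genes, sets 2yo replicates 1, 2 and 3 against the young arrays joined by 2yo replicate 4, and so follows the hybridisation control class (191 genes pass in the fit with that class as a block). For 2yo against 1yo 1 of 35 splits reached 4 genes, and the highest other called 0. Within the 7 arrays with low controls 1 of 35 reached 1488, and the highest other called 9.

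The list counts stood out less. For 1yo against young 2 of 35 splits called as many lists as the real 13 (highest other 14), for 2yo against young 4 of 35 reached 12 (highest other 13), and for 2yo against 1yo 28 of 35 reached 6 (highest other 13). For the F test 1 of 100 splits reached 7627 genes (highest other 3393), and for the overlap 1 of 100 reached 6961 (highest other 1012). Here too the ages go largely with the control class, so neither count parts them.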

How the results depend on the processing

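The tests with the hybridisation controls or with arrays left out by quality were chosen after the result was seen, and the others before. The main counts were 8820 genes for 1yo against young, 7225 for 2yo against young, 4 for 2yo against 1yo, 7627 in the F test and 6961 in the overlap, with 13, 12 and 6 lists. A list counts as reversed when the direction of its test turned and it passed in at least 1 of the fits compared, and the value given is its median. The cause of a difference between settings was not tested.

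Quantile normalization gave 5685 and 4337 genes against young and 4313 in the F test, with 7 lists at 2yo. Cyclic loess gave 5390 (2577 up, 2813 down), 3937 (1866 up, 2071 down) and 14 genes, 4485 in the F test, and 4 and 5 lists against young. By removing offsets along intensity it sets the even balance itself, so it cannot tell a true shift of most genes from a technical one. Under cyclic loess some lists reversed: oxidative phosphorylation to -0.2 at 1yo and -0.186 at 2yo, and beta cell identity to -0.174 at 2yo. So did Igf1r at 1yo (-0.0139), Ppy at 1yo (-2.3, and -1.45 with quantile normalization), Nkx6-1 at 2yo (-0.11) and Cdkn1a at 2yo (-0.231).

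Probe sets taken one by one gave 13420 at 1yo. The mean of probe sets reversed Cryl1 to 0.403 at 1yo and 0.277 at 2yo, and leaving out probe sets marked for cross-hybridisation reversed Erdr1 at 2yo to -2.05. An intensity trend with robust variance gave 7 genes for 2yo against 1yo, and array weights 2756. Fitting only the 2 groups gave 3890 for 2yo against young and 9 for 2yo against 1yo.

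With an estimated correlation 0 lists passed in each comparison. With fry 13 lists passed for 1yo against young, 14 for 2yo against young and 0 for 2yo against 1yo. The test turned upward for the imprinted list (median 0.621 at 1yo and 0.621 at 2yo) and the duct list at 1yo (median -0.334). At 1yo and 2yo the acinar (adjusted p of 0.468 and 0.271) and myeloid lists (0.537 and 0.331) did not pass by fry. Neither did the lymphoid (0.0843 and 0.19) and disallowed lists (0.0843 and 0.203), nor the senescence list at 1yo (0.0648). The cell cycle inhibition, marker, imprinted and duct lists passed by fry and not by camera at both ages. So did the antioxidant list at 1yo and the insulin and dissociation lists at 2yo.

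The replicate number as a block gave 2 genes for 2yo against 1yo, 8812 and 7447 against young, 7562 in the F test, and 13, 15 and 9 lists. The correlation of the same-number pairs ran from -0.57 to 0.302 over 10 pairs, with 4 above 0.1. Pairs with different numbers ran from -0.477 to 0.549. The shared numbers thus gave no sign of pairing, which a check on so few arrays cannot exclude.

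Leaving out 1 array at a time gave 7447 to 9757 genes for 1yo against young, 5092 to 9420 for 2yo against young, 2 to 72 for 2yo against 1yo, 6213 to 9336 in the F test, 5023 to 8898 in the overlap, and 11 to 15, 11 to 12 and 5 to 9 lists. The 72 came without 2yo replicate 4, and 2 without each 1yo replicate and without 2yo replicates 2 and 3. The 9 lists came without young replicate 3 and again without 2yo replicate 3. Leaving out both young replicate 3 and 2yo replicate 4 gave 10148 and 9950 genes against young and 453 for 2yo against 1yo.

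With the control class as a block the counts were 92, 191 and 72 genes, 158 in the F test, 58 in the overlap, and 8 and 6 lists against young. Lists that reversed at 1yo were dissociation 0.375, acinar 7.28, myeloid 1.3 and lymphoid -0.214. At 2yo they were interferon 0.126, acinar 3.25 and myeloid 0.803. Genes that reversed at 1yo were Reg3b 4.07, Ptf1a 0.588, Igf1r -0.523 and Kcnq5 0.0539, and at 2yo Igf1r -0.0289.

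With the control mean as a covariate the counts were 59, 3 and 52 genes, 71 in the F test, 3 in the overlap, and 4 and 0 lists against young. Reversals at 1yo were dissociation 0.202, acinar 4.29, myeloid 0.67, lymphoid -0.0809, Reg3b 2.5, Ptf1a 0.185 and Igf1r -0.446. At 2yo they were interferon -0.46, acinar 2.69, myeloid 0.444, lymphoid 0.0037, Nrsn2 0.187, 2810408B13Rik 0.252, Cryl1 0.178 and Igf1r -0.445.

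With the class as a block and without young replicate 3 the counts were 1303, 1750 and 453 genes, 1847 in the F test, 1006 in the overlap, and 7 lists at 1yo. Reversals at 1yo were dissociation -0.166, acinar 4.42, myeloid 0.699, lymphoid 0.0163, Reg3b 2.67, Ptf1a 0.286, Igf1r -0.591 and Kcnq5 0.0202. At 2yo they were interferon 0.0281, myeloid 0.274, lymphoid -0.0917 and Igf1r -0.0971.

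Using only the 4 arrays with high controls, 0 genes passed between 2yo and young with limma (227 at an unadjusted p under 0.05) and 6 lists. Reversals were interferon 0.126, acinar 3.25, myeloid 0.803, lymphoid -0.112 and Igf1r -0.0289. Using only the 7 arrays with low controls, 1488 genes passed between 2yo and 1yo.

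Over all values under the planned settings, those above included, 2592 of single genes were the same, 69 weaker, 58 stronger and 8 reversed. For lists these counts were 1481, 102, 64 and 6. Weaker means that a call was lost and stronger that a call was gained. Same covers values that passed in neither fit, even where the direction turned, as for Ins2 at 1yo after cyclic loess (-2.3). It therefore does not measure how stable the directions were. Under the settings added later these counts were 267, 210, 84 and 18 for genes and 237, 39, 20 and 26 for lists.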

Other observations

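The tests of explanations in this part were written after the result was seen, and the comparison of 2yo replicates 1, 2 and 3 with 1yo was chosen after the data had been seen. Among the 7 arrays with low hybridisation controls, Lcn2, an iron-binding protein of innate defence, was higher at 2yo by at least 5.43 (adjusted p = 1.76e-09), since at 1yo it lay within the range of the Bacillus control probe sets. The interferon-induced genes Ifit3, Ifit1 and Oasl2 were higher by 3.56, 3.07 and 2.60, and Irf7, a transcription factor of that response, by 2.18. The class I MHC genes B2m, H2-D1 and H2-K1 were higher by 3.04, 1.72 and 1.49, the immunoproteasome gene Psmb9 by 1.35 and the chemokine Cxcl10 by 2.85. The stress genes Trib3, Ddit3, Chac1 and Atf3 were higher by 2.27, 1.47, 1.25 and 1.09, and the cell cycle inhibitor Cdkn1a by 1.07, in lists that did not pass (unfolded protein response with 7 higher and 0 lower, adjusted p = 0.21; cell cycle inhibition with 2 higher and 4 lower, adjusted p = 0.444). Lcn2, Oasl2, B2m, H2-D1 and Psmb9 were chosen after their values were seen.

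In the same comparison the serotonin enzymes Tph1 and Tph2 were lower by -1.80 and -1.48, the glucose transporter Slc2a2 by -1.14, the GABA enzyme Gad1 by -2.13, the transcription factor Nkx6-1 by -0.60 and Ucn3, a peptide of mature beta cells, by -0.47. Txnip, a glucose-induced regulator of redox state, was lower by -2.37. Of 20 beta cell identity genes 0 were higher and 7 lower (list adjusted p = 8.01e-05, and 0.215 with an estimated correlation). Of 23 interferon genes 21 were higher and 0 lower (median 1.35, list adjusted p = 2.86e-28, and 0.00144 with an estimated correlation). Markers of other cells differed in the same comparison: of 17 acinar genes 11 were lower (median -4.13, list adjusted p = 5.2e-10, and 0.643 with an estimated correlation) and of 17 myeloid genes 6 were lower and 1 higher (list adjusted p = 5.1e-05, and 0.661 with an estimated correlation), while of 5 duct genes, Lcn2 among them, 3 were higher and 0 lower (list adjusted p = 0.0228, and 0.215 with an estimated correlation). The hybridisation controls of the groups did not overlap here either, with 10.93 the lowest at 1yo and 10.64 the highest at 2yo. Tph2, Slc2a2, Gad1 and Ucn3 were chosen after their values were seen.

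Most genes that passed the filter read higher at 1yo and 2yo than in young in the deposited values. After cyclic loess the medians were -0.0133 and -0.00999, but that method removes such offsets by design, so these values decide nothing. A technical difference between arrays with high and low hybridisation controls could explain the higher readings and stays open. The array 2yo replicate 4 lay at 0.351 of the way from the young mean to that of the other 2yo arrays. Those lay at 1.08, 0.936 and 0.968 when set against each other. The place of 2yo replicate 4 near young had prompted the test and so decides nothing. The pattern does not need that array, since the median of the genes tested from young to 2yo was 0.965 without it and the 1yo group does not contain it, which argues against a wrong label there as its cause. Whether the label is right stays open, and every blocked value against young depends on it. Labelling arrays of all ages in the same batch would test the technical difference but would not settle that label. Acinar list means were also high on young replicates 1 and 2 and 2yo replicate 4 (12.77, 12.75 and 13.21), though not on young replicate 3 (5.151). Whether acinar content bears on the higher readings at 1yo and 2yo was not tested.

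Acinar enzyme transcripts were high in young replicates 1 and 2 and in 2yo replicate 4, where Cela3b, Clps and Ctrl stood at 14.76, 13.65 and 14.52. Acinar cells or their RNA carried through the sort may be the source, which stays open: the 17 genes moved together across arrays (percentile 100 among 10000 random lists), but this restates what prompted the test and decides nothing. The acinar list did not pass between 2yo and 1yo with that array (adjusted p = 0.375) and fell without it (median -4.13, adjusted p = 1.58e-10, and adjusted p = 0.53 with an estimated correlation). The control class explained a share of 0.392 of the variation of the acinar mean. That share includes young replicate 3 (5.151, with high controls), which correlated weakly with the other arrays, and it was not computed without that array. Among the 7 arrays with low controls the acinar mean still ran from 3.637 to 10.35, which argues against the class as the whole cause. A second GFP sort with a check of acinar enzymes would remove this source.

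Interferon genes were higher in 2yo replicates 1, 2 and 3 than at 1yo. Immune cells carried through the sort could raise them, but the median difference of 24 myeloid and lymphoid markers was -0.507, which argues against it. Lower readings on 2yo replicate 4 could hide the response there, which stays open. The list fell by 1.98 to that array, against a median of 1.02 in random lists (percentile 100). Its low values there had been seen before the test was written, and the random lists were matched on level alone, so this decides nothing. Age, batch and the state of single animals were not tested and remain open.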
